A study of Saccharomyces cerevisiae with 9 samples.

How the data were processed

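Pools of Saccharomyces cerevisiae deletion strains, each marked by short DNA tags, were compared on 2-colour tag arrays after growth with and without sodium arsenite. Per the labels' protocols, tags were amplified from phenol-chloroform extracted genomic DNA by asymmetric PCR with labelled primers, the control culture was labelled with Cy5 and the arsenite culture with Cy3 on all 9 arrays, and both cultures of an array were started from the same cells. No dye swap is labelled, so a bias of a tag toward a dye stays in every single-array value and cancels only in a slope over doses or in a difference between arrays.

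The deposited value of a tag probe is a log ratio of the 2 channels; the authors' scale, centring and direction are not given in the sources used here, nor are the scanner software, the normalization and the filters. The deposited values were taken as log2, since base 10 would require ratios beyond the range of a scanner; the natural log could not be ruled out, and with it every printed log2 value would be larger by a constant factor. Medians of the deposited values per array lay between -0.09 and 0.12 on 8 arrays and at 2.99 on the haploid 1600 µM array. Values were turned so that negative means fewer arsenite-grown than control cells, then centred on each array's median strain, so that all values are relative to the median of that array.

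The direction is called likely, not settled. The check fixed for it used the pfd1 array, whose arsenite medium lacks uracil while the control medium contains it. The 4 uracil synthesis strains had a median of -4.60 there, lower than all 10000 random lists of 4 strains. The second part of the check, strains deleted within 20 genes of PFD1, did not lie at an end (34 strains, median 0.06, percentile 71.9 among random lists). By the labels both channels of this array carry the PFD1 null mutation, so linkage to it could not separate the channels. That departs from the plan, which required both parts. The remaining basis is the order of the haploid arrays, where the arsenite exporter strain and the strains of arsenite entry genes moved to opposite ends with dose. With the sign turned, every loss given here would read as a gain.

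Of 22575 probes in the value table, 9727 had a value on at least 1 array. The platform annotation names 1 gene for 8765 of these and none for 962, and 0 probes name several; 8 of the 18794 annotated probes did not match a gene of the reference table (assembly R64) and 0 symbols needed an update. Symbols without a standard name are systematic names. The named probes gave 5101 strains, 3541 with at least 2 tags and 1560 with 1 tag; 79 had more than 2 probes. A strain's value is the mean of its tag probes. The annotation does not say which probes are UpTags and which DnTags, so probes were split by their position in the table into tag set 1 and tag set 2 (an offset of 10971 between the probes of a strain), which took the place of UpTag and DnTag in the alternatives. No column was left unmapped.

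Each pool and dose has 1 array, so no comparison between doses has a replicate check. In the haploid pool the test was the slope of the strain value per dose step (0, 100, 200, 400, 800 and 1600 µM taken as equal steps), fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05) over strains measured on every array of the fit. Dose order is the only replication: a p-value tests a slope of 0 against the scatter around a straight line, so a response that is not straight counts as scatter. A fit of the 5 arrays from 0 to 800 µM was added after the 1600 µM array was seen to stand apart. On simulated data the 6-array fit recovered 80% of 100 strains given a slope of 0.5 and 95% of 100 given a slope of 1, with 5 false calls among 2507 strains. The 5-array fit recovered 85% and 89%, with 10 false calls among 3731. Simulated responses were exactly straight, so these rates do not cover responses that bend with dose.

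In all, 23 gene lists were fixed: prefoldin, CCT chaperonin, phosducin-like and prefoldin-like, tubulin folding and tubulin, actin cytoskeleton, arsenite export and vacuolar sequestration, arsenite entry, HOG pathway, glutathione and redox, sulfur assimilation, vacuolar ATPase, ESCRT, HOPS with CORVET and retromer, proteasome 20S core, proteasome regulators, Hsp70 with Hsp90 and disaggregase chaperones, Elongator and tRNA wobble modification, homologous recombination and DNA damage, SWI/SNF with SAGA and Mediator, ergosterol synthesis, uracil synthesis, mitochondrial ribosome and cytosolic ribosome. Lists with at least 3 measured members were tested on the slopes with camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation. The second form also takes its degrees of freedom from the few arrays instead of the many strains. A list that does not pass it therefore need not hold correlated strains. Beside camera stands fry, which asks whether a list's strains moved one way on balance. On single arrays a list is described by the percentile of its median among 10000 random lists of its size, with no p-value. A further 10 lists were drawn up after the values were seen.

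The background range of the haploid pools is the 0.5th to 99.5th percentile of the haploid 0 µM array, where both cultures grew without arsenite. It ran from -1.39 to 1.37, and that of the heterozygous pool, from its own 0 µM array, from -0.873 to 1.125. The heterozygous effect is the 450 µM value minus the 0 µM value. The pfd1 pool has no 0 µM array analysed here, so its ratio mixes arsenite, the PFD1 null background and the uracil selection; no probe reads the PFD1 disruption itself. The spread between tags of a strain gave an error of 0.20 to 0.30 log2 units for a strain with both tags on an array. For the heterozygous difference the error was 0.315 with both tags and 0.446 with 1 tag. These errors cover tags, not cultures.

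The rule for naming strains took the 12 steepest slopes in each direction past the threshold that lay on the same side of the 0 µM value at 3 or more doses and in both tags (filled up to 6 with strains that missed it), the 10 largest changes in each direction on the other pools whose tags lay outside the central 90% of strains, all measured members of the lists nearest to the study's subject, and the extreme 1 to 4 members of the others. Strains named for their rank at a single dose were chosen after their values were seen.

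There were 27 alternatives fixed, on the dose scale, centring and scaling, tags, filters, moderation, the background range, the inter-gene correlation and each array left out; a fit to the same probes on every array and one without chromosome arm III right were added after seeing the data. Gene coordinates are not printed, since the build behind the annotation is not given in the sources used here. Tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.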

Results

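The abundance of tagged yeast deletion strains was measured on 9 arrays, each comparing an arsenite culture with a control culture split from the same cells. Of these, 6 held haploid strains, obtained as spores of a heterozygous diploid pool and grown to confluence at 30 °C on plates selecting haploid progeny, with 0, 100, 200, 400, 800 or 1600 µM sodium arsenite. A further 2 held the heterozygous diploid pool, in which 1 of the 2 gene copies is deleted, grown in liquid medium for 10 generations with 0 or 450 µM. The last held haploids that also lack PFD1, a prefoldin subunit, at 5 µM. There are no replicates, and the number of arrays limits the precision of every value. Between 3713 probes (haploid 1600 µM) and 8879 probes (heterozygous 450 µM) gave a value per array, and between 2508 and 4904 strains. Values are log2 ratios of arsenite over control relative to the array's median, so a negative value is a relative loss under arsenite; the direction is likely, on the basis given with the processing.

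The haploid series asked which nonessential genes a cell needs to grow in arsenite, and at what dose. Strains below the background range of the 0 µM array numbered 34 of 4089 at 100 µM, 64 of 4171 at 200 µM, 237 of 4122 at 400 µM and 468 of 3956 at 800 µM, against 20 of 3905 on the 0 µM array itself. Strains above it numbered 15, 35, 34 and 291 at the same doses. The correlation across strains between tags of the same strain was 0.142 at 0 µM and 0.880 at 800 µM.

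**Figure D1:**
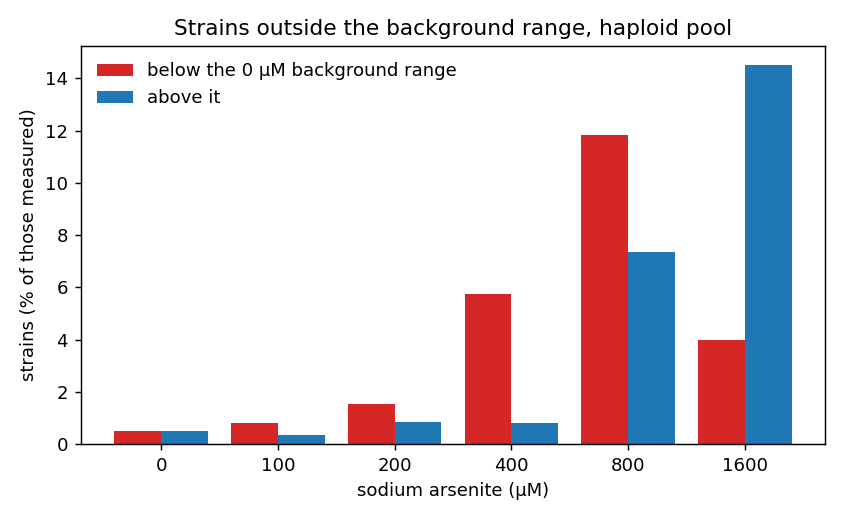
Percentage of strains below and above the background range of the haploid 0 µM array at each arsenite dose (µM) of the haploid pool, 1 array per dose. The share below the range is 0.83% at 100 µM and 11.83% at 800 µM, and 3.99% at 1600 µM, where fewer strains had a value.

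Strains lacking prefoldin, the hexameric cochaperone that hands unfolded actin and tubulin to the CCT chaperonin, were among the strains most depleted at the lowest dose. At 100 µM all 6 prefoldin strains lay within the 9 lowest of 4089, beside the arsenite exporter ARR3 at -5.51, its activator ARR1 at -3.69 and MAG1, which stood at -3.30 without arsenite. PAC10 read -4.95, GIM4 -4.50, PFD1 -4.06, YKE2 -3.74, GIM5 -3.36 and GIM3 -3.29; the 4 of them measured at 0 µM lay between -0.43 and 0.01. All 6 stayed below the background range at 200, 400 and 800 µM, with list medians of -4.02, -5.46 and -4.92. As a list prefoldin fell along 0 to 800 µM (4 strains with a value at every dose, median slope -1.15 per dose step, camera adjusted p = 0.00584, but adjusted p = 0.315 with an estimated correlation and fry adjusted p = 0.0843). None of the 4 passed limma's threshold over all strains (adjusted p from 0.0655 for GIM5 to 0.125 for PAC10), while all 4 passed adjusted over the list alone; most of their loss was reached at the first dose, which a slope per step describes poorly.

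Of the chaperonin itself, an essential complex of 8 kinds of subunit, only CCT2 and CCT5 had haploid values, with slopes of -0.13 (adjusted p = 0.352) and -0.15 (adjusted p = 0.376). Haploid strains lacking an essential gene should not grow, so what these tags measure in the haploid pools is uncertain. BUD27, a prefoldin-like protein, read -1.41, -2.66 and -1.96 at 200, 400 and 800 µM (slope -0.75, adjusted p = 0.0626), and no other member of its list had a value.

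Strains of the tubulin folding path fell with dose. CIN1, a tubulin-folding cofactor, read -2.27, -4.14, -6.23 and -6.60 at 100, 200, 400 and 800 µM (slope -1.66 ± 0.14 SE, adjusted p = 0.0117). CIN2 had a slope of -1.57 ± 0.15 (adjusted p = 0.0215) and TUB3, the minor alpha-tubulin, of -1.46 ± 0.08 (adjusted p = 0.00169). CIN4 missed the threshold with a slope of -0.52 (adjusted p = 0.0581), and RBL2, a beta-tubulin binding protein without a 0 µM value, read 0.54, -0.52, -2.92 and -4.46 from 100 to 800 µM. ALF1, a cofactor that binds alpha-tubulin, lay on the other side with 2.36 at 800 µM (slope 0.40, adjusted p = 0.0994) but also 0.99 at 0 µM. The essential tubulin gene TUB1 had a value only at 0 µM, and TUB2 and PAC2 had none in this series. Over the list, 3 of 5 strains fell and 0 rose, or 4 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.00157; adjusted p = 0.271 with an estimated correlation; fry adjusted p = 0.00355). Of 14 actin cytoskeleton strains CAP1, which encodes a capping protein subunit, fell over all strains (slope -0.41 ± 0.06, adjusted p = 0.0374), and 6 fell adjusted over the list alone. That list's median slope was -0.07 and its mean -0.26 (camera adjusted p = 0.0177; adjusted p = 0.271 with an estimated correlation), with ARC18 of the Arp2/3 complex steepest at -1.12 (adjusted p = 0.0622).

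Genes that move arsenite across membranes stood at both ends. ARR3, which exports arsenite at the plasma membrane, read -5.51 at 100 µM and -6.90 at 200 µM, the lowest strain at each of these doses, and -6.52 at 800 µM (slope -1.40, adjusted p = 0.138). ARR1, the transcription factor that induces ARR3, read -5.19 at 800 µM and ARR2, the arsenate reductase, -4.59; neither slope passed (adjusted p = 0.158 and 0.0626). YCF1, which moves glutathione conjugates into the vacuole, fell with a slope of -1.05 ± 0.18 (adjusted p = 0.0478), and YAP1, a transcription factor of the stress response, with -1.22 ± 0.18 (adjusted p = 0.0395). The export list fell (2 of 5 over all strains, 5 of 5 adjusted over the list alone; camera adjusted p = 0.00125; adjusted p = 0.271 with an estimated correlation). The entry list rose: FPS1, the aquaglyceroporin through which arsenite enters, read 4.19 at 800 µM, and its activators RGC1 and ASK10 (also called RGC2) 1.67 and 4.74. RGC1 passed over all strains (slope 0.50 ± 0.05, adjusted p = 0.0243), FPS1 and ASK10 did not (adjusted p = 0.0652 and 0.0638), and all 3 passed adjusted over the list alone (camera adjusted p = 0.00178; adjusted p = 0.271 with an estimated correlation). ASK10 and FPS1 were the highest strains of the 800 µM array.

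**Figure D2:**
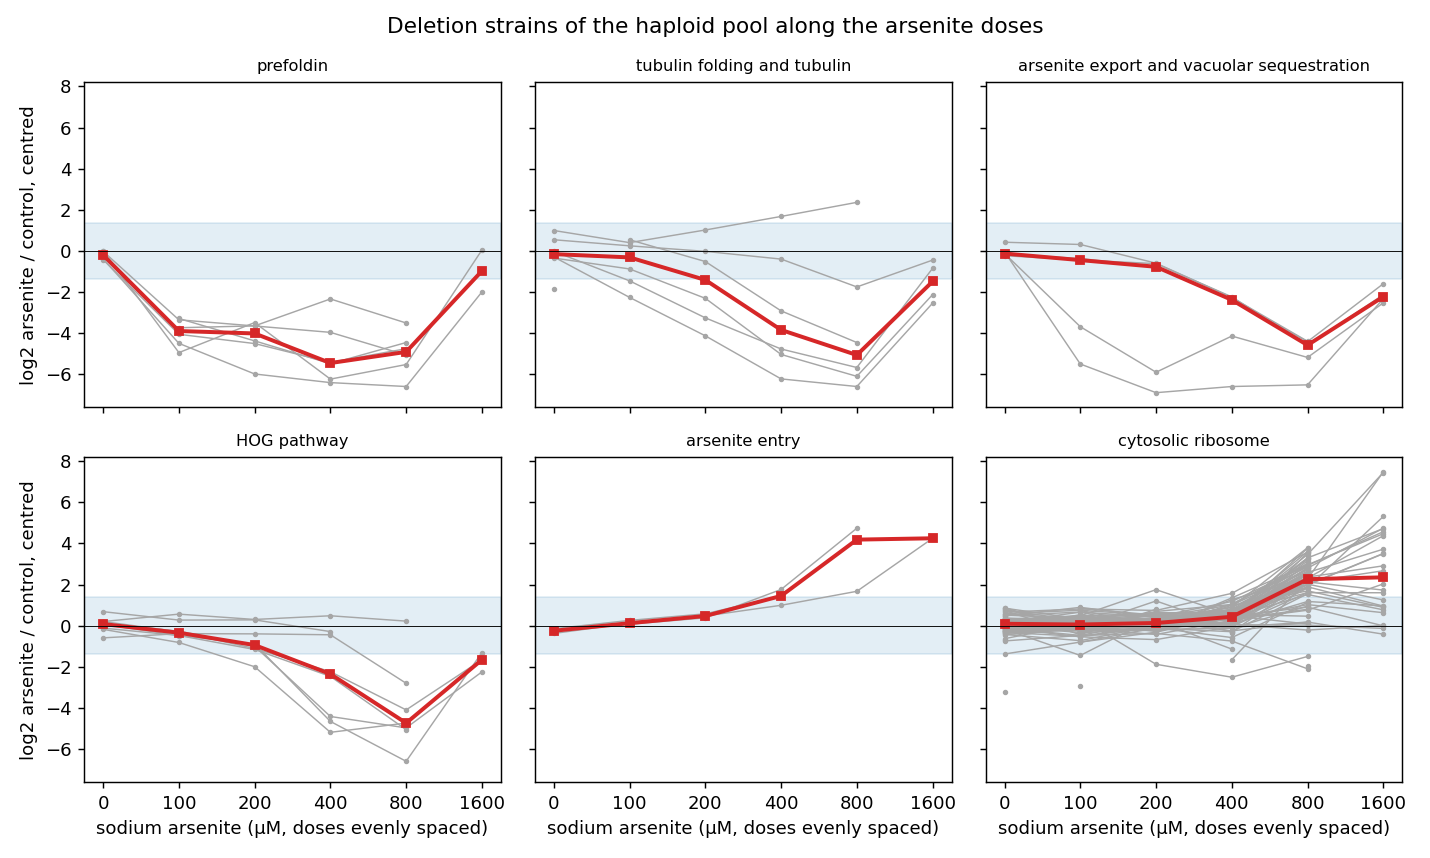
Log2 ratio of arsenite over control against dose (µM, equal steps) in the haploid pool for 6 gene lists; gray lines are member strains, the red line is the list median and the blue band is the background range of the 0 µM array. The prefoldin median is -3.90 at 100 µM, while the tubulin folding median is -0.32 there and -5.07 at 800 µM.

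The HOG pathway, the kinase cascade that also closes the FPS1 channel, fell with dose in the branch that runs through SSK1. SSK1 had the steepest slope of all named strains at -1.71 ± 0.28 (adjusted p = 0.0464), followed by the kinases SSK2 at -1.43 ± 0.22 (adjusted p = 0.0429), PBS2 at -1.35 ± 0.21 (adjusted p = 0.0432) and HOG1 at -1.22 ± 0.18 (adjusted p = 0.0395). STE50, an adaptor of the other branch, fell too (slope -1.05 ± 0.12, adjusted p = 0.0265). SHO1, the sensor of that branch, had a slope of -0.45 (adjusted p = 0.237) and SSK22, a paralogue of SSK2, of -0.004 (adjusted p = 0.976). In all 5 of 7 strains fell, and the same number adjusted over the list alone (camera adjusted p = 0.00024; adjusted p = 0.271 with an estimated correlation).

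Other lists fixed in advance shifted as well. Homologous recombination and DNA damage strains fell (5 of 22, and 13 adjusted over the list alone; median slope -0.37; camera adjusted p = 0.000603). The steepest that passed were MRE11 at -0.87, XRS2 at -0.83 and RAD52 at -0.82, all of double-strand break repair, and RAD50 at -0.85 missed the threshold (adjusted p = 0.07). SWI/SNF, SAGA and Mediator strains fell (3 of 15, and 6 over the list alone; median -0.24; camera adjusted p = 0.00198), with the acetyltransferase GCN5 at -1.23 and SNF5 at -0.51. Ergosterol strains fell (1 of 8, and 4 over the list alone; median -0.42; camera adjusted p = 0.00568), with the sterol methyltransferase ERG6 at -1.25 passing and at -5.22 at 800 µM. ESCRT strains, which sort membrane proteins to the vacuole, fell as a list (1 of 15, STP22 at -0.44; over the list alone 9 fell and 1 rose; camera adjusted p = 0.0226). Mitochondrial ribosome strains fell (6 of 40, and 19 over the list alone; median slope -0.34; camera adjusted p = 6.32e-09), and 21 of the 44 measured lay below the background range at 800 µM. With an estimated correlation none of these 5 lists passed by camera (adjusted p = 0.315 for DNA damage and 0.271 for the others). In ESCRT the estimate itself was -0.064, below the preset 0.01. Lists that camera did not call at the preset correlation were HOPS with CORVET and retromer (adjusted p = 0.068), vacuolar ATPase (0.0701), Elongator (0.267), Hsp70 with Hsp90 and disaggregase chaperones (0.272), proteasome regulators (0.405), glutathione and redox (0.600), sulfur assimilation (0.765) and uracil synthesis (0.997). Single strains within them still fell, among them the polyubiquitin gene UBI4 (slope -1.38), VPS33 (-0.72) and CCS1 (-0.73), the copper chaperone of the superoxide dismutase SOD1 (-0.73, adjusted p = 0.101). Of the proteasome 20S core only PRE9 was measured at every dose up to 800 µM (slope -0.17, adjusted p = 0.369).

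Cytosolic ribosome strains moved the other way. Their median was 0.09 at 0 µM, 0.43 at 400 µM and 2.26 at 800 µM, where 52 of 69 lay above the background range. The list rose along 0 to 800 µM (median slope 0.48 over 62 strains, camera adjusted p = 1.22e-11; adjusted p = 0.342 with an estimated correlation; fry adjusted p = 0.125). Of its strains RPL37A (slope 0.92 ± 0.13, adjusted p = 0.0395), RPS7B (0.56, adjusted p = 0.0421) and RPL36A (0.48, adjusted p = 0.0472) rose over all strains, and 4 rose adjusted over the list alone. RPL14A (-0.75) and RPL32 (-0.42) had negative slopes that missed the threshold (adjusted p = 0.107 and 0.094).

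Across all strains from 0 to 800 µM, limma called 108 of 3731 lower and 8 higher. After SSK1, CIN1 and CIN2 the steepest losses were in BUL1, an adaptor of the ubiquitin ligase Rsp5 (slope -1.49 ± 0.17, adjusted p = 0.0277), BUD31, a splicing factor (-1.49 ± 0.22, adjusted p = 0.0417), MCK1, a kinase of the GSK-3 family (-1.48 ± 0.23, adjusted p = 0.0432), TUB3, SSK2, UBI4, LTE1, a regulator of mitotic exit (-1.37 ± 0.06, adjusted p = 0.00151), PBS2 and IRA1, an inhibitor of Ras (-1.32 ± 0.15, adjusted p = 0.0277). The gains, besides those of the 3 ribosomal strains and RGC1, were in DBF20 (0.47), YLR225C (0.45), the tRNA methyltransferase TRM9 (0.37) and NEL1 (0.32). Quantile normalization gave 43 lower and 32 higher, with 20 of the 116 calls kept, and scaling by the median absolute deviation 145 and 49, with 71 kept, whereas limma with a trended and robust prior, or the arsenite arrays set against the 0 µM array alone, called 0 in each direction. Without the 100 µM array 7 strains were lower and 0 higher, without the 200 µM array 55 and 1, without 400 µM 14 and 1, and without 800 µM 31 and 1.

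With the 1600 µM array included, as the test had been planned, limma called 0 of 2507 strains in either direction (256 lower and 418 higher at an unadjusted p under 0.05). The strains with the lowest unadjusted p, which are not the steepest, were SMY1 (-0.31), YPL077C (-0.30), BCK2 (-0.47), CAP1 (-0.33), GET3 (-0.39) and DIT1 (-0.31) on the lower side. On the higher side they were COG8 (0.43), PER33 (0.40), RPL36A (0.45), FUS3 (0.47), PHO80 (0.38) and NEJ1 (0.32). All had a limma adjusted p of 0.102. Of 16 lists only the cytosolic ribosome rose (26 strains, median slope 0.48, camera adjusted p = 1.59e-07; adjusted p = 0.646 with an estimated correlation). This array stood apart: its deposited median was 2.99 toward loss, 2508 strains had a value, and 364 lay above the background range against 100 below it. Its values are relative to that median, so a strain at 2.99 there has a deposited ratio of 0. CIN1, ARR1 and ARR3 were among its 5 lowest strains at -2.55, -2.53 and -2.33. Other strains far down at 800 µM lay near the median: PAC10 read 0.04 after -5.53, UBI4 -0.11 after -5.01 and TUB3 -0.85 after -5.68. At the high end NMD2, of nonsense-mediated decay, reached 10.3 and NPR2, a brake on TORC1, 8.09. RGC1 read 4.25.

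In the heterozygous diploid pool essential genes can be assayed, so this comparison asked whether losing 1 copy of a chaperonin gene matters at 450 µM. The chaperonin strains were low: CCT7 at -1.56, TCP1 at -1.19, CCT5 at -1.05, CCT2 at -0.71 and CCT4 at -0.54 (450 µM minus 0 µM). Their median of -1.05 was lower than all 10000 random lists of 5 strains, and 4 of the 5 lay below the background range at 450 µM. CCT3, CCT6 and CCT8 had no value. TCP1, CCT5 and CCT2 rest on 1 tag each, where the error of the difference is 0.446, against 0.315 with both tags. The export list had a median of -0.94 (percentile 0.00), with ARR3 at -2.17, ARR1 at -1.53, YCF1 at -0.94, YAP1 at -0.16 and ARR2 at 0.40. HOG strains had a median of -0.35 (percentile 0.56), with SSK2 at -1.58, SSK1 at -1.31, HOG1 at -1.25 and PBS2 at -1.10, whereas YPD1, which acts upstream of SSK1 to hold it inactive, read 1.49. At the other end were the entry list, with a median of 1.06 (percentile 99.99, with ASK10 at 1.11, RGC1 at 1.06 and FPS1 at 0.22), and the cytosolic ribosome (median 0.37 over 92 strains, percentile 100.00). On the 450 µM array alone the medians were -1.15 for the chaperonin, -0.55 for export and -0.18 for HOG. They were 0.64 for entry and 0.32 for the cytosolic ribosome (107 strains).

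Prefoldin strains, far down in the haploid pool, had a median of -0.28 here (5 strains, percentile 7.99), from PAC10 at -0.71, GIM4 at -0.53 and GIM3 at -0.28 to GIM5 at -0.01 and PFD1 at 0.07. Tubulin strains had a median of 0.01 (percentile 54.2), although RBL2 read -1.68, PAC2 -1.30 and TUB3 -1.28; CIN1 stood at 0.46, TUB1 at 0.43, CIN2 at 0.05, CIN4 at 0.02, ALF1 at 0.01 and TUB2 at 0.00. Actin strains had a median of -0.01 (percentile 49.6), with ACT1 itself lowest at -0.68. BUD27 read 0.74. Of the 22 lists with enough members, the 3 low and 2 high lists named here were those outside the central 95% of random lists.

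The strains with the largest losses were CDC19, pyruvate kinase (-4.40), PRO1, of proline synthesis (-3.87), RXT2, of a histone deacetylase complex (-3.05), ADE12, of adenine nucleotide synthesis (-2.73), TUB4, the gamma-tubulin gene (-2.47), RSC6 (-2.38), TUP1 (-2.31), YIH1 (-2.30), CNA1 (-2.28) and PCF11 (-2.24); CDC19, PRO1, RSC6 and YIH1 rest on 1 tag measured on both arrays. RSC6, TUP1 and YIH1 lie on the right arm of chromosome III, where 22 of 77 strains (28.6%) read below -1 against 1.5% of strains elsewhere. The largest gains were in RPL13B (1.84), SIP1 (1.73), RSA3 (1.67), RPL10 (1.57), RPL14A (1.56), TOS7 (1.55), SPT6 (1.53), YPD1 (1.49), SDH2 (1.47) and PUB1 (1.46), each resting on 1 tag measured on both arrays; for SIP1 and RSA3 that tag alone gave 0.79 and 0.64. On the 450 µM array RPL13B (0.75), RSA3 (0.98), YPD1 (1.08), SDH2 (0.85) and PUB1 (0.18) lay inside the heterozygous background range. Their gains therefore rest in part on low 0 µM readings, which for PUB1 (-1.28) and RPL13B (-1.09) lay below that range. The other strains with the largest gains lay above the range at 450 µM. None of these differences, losses or gains, has a replicate check.

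**Figure D3:**
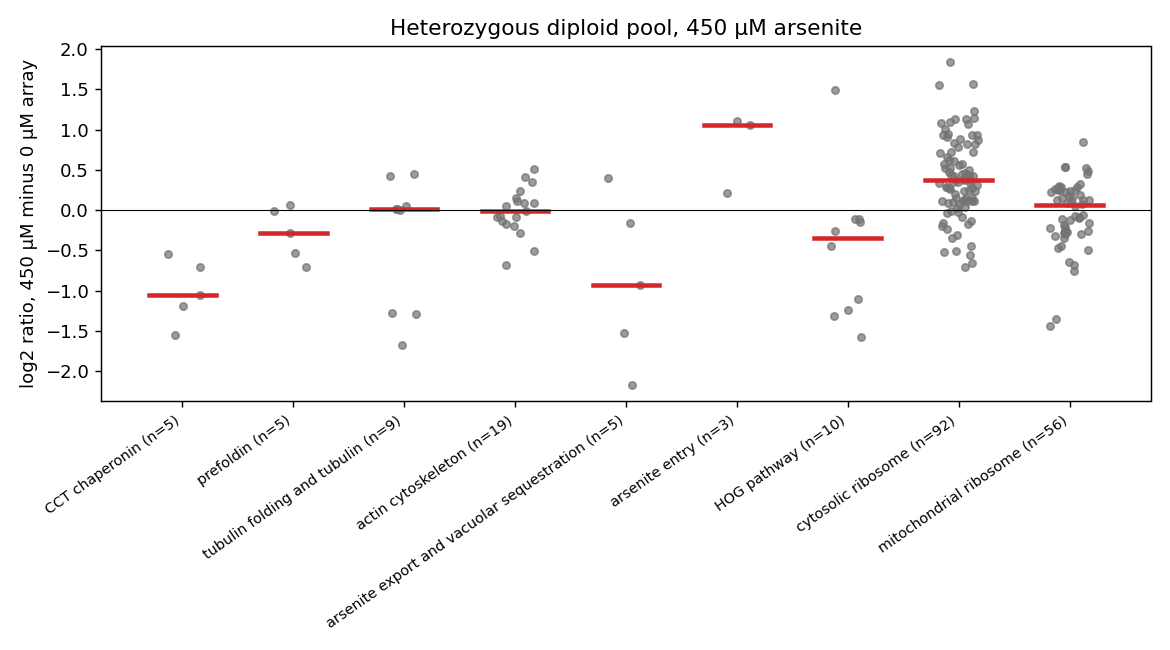
Log2 ratio at 450 µM minus that at 0 µM for the strains of each gene list in the heterozygous diploid pool, 1 array per dose; points are strains and bars are list medians. The CCT chaperonin median is -1.05 and the arsenite entry median 1.06.

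In haploids lacking PFD1 the question was which second deletions matter once prefoldin is already lost, at 5 µM arsenite. The control medium held uracil and the arsenite medium did not, and the ratio does not separate the 2 differences. The uracil synthesis strains stood at the bottom, with URA1 at -5.23, URA2 at -4.88, URA5 at -4.32 and URA4 at -3.98. The other 5 prefoldin strains and the PFD1 strain lay between -0.26 and 0.57 (median -0.14, percentile 26.8), with none outside the background range: YKE2 -0.16, PAC10 -0.12, GIM3 -0.26, GIM4 0.57, GIM5 -0.26 and PFD1 -0.11. Since all cells of this pool already lack PFD1 by the labels, the PFD1 tag cannot report a second deletion, although the median includes it.

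Tubulin strains had a median of -1.74 (8 strains, lower than all random lists), with CIN4 at -3.95, RBL2 at -3.31, CIN1 at -2.07, ALF1 at -2.04, TUB3 at -1.44 and CIN2 at -1.41 all below the background range, and TUB1 and TUB2 at 0.72 and 0.71. Export strains had a median of -1.86 (percentile 0.02), with ARR1 at -4.58, ARR3 at -1.89, YAP1 at -1.86, ARR2 at -1.35 and YCF1 at -0.89. Vacuolar ATPase strains (median -0.73, percentile 0.01), actin strains (-0.38, percentile 0.42, RVS161 lowest at -3.12) and ESCRT strains (-0.36, percentile 1.11) were low too. At the other end lay the cytosolic ribosome (median 1.78, percentile 100.00, 59 of 95 above the background range), the proteasome regulators (1.17, percentile 100.00, with SEM1 at 2.94, IRC25 at 2.85, UBP6 at 2.67 and RPN10 at 2.59), the Hsp70, Hsp90 and disaggregase chaperones (0.46, percentile 99.8, STI1 highest at 2.42) and arsenite entry (0.95, percentile 97.7; FPS1 1.68, ASK10 0.95, RGC1 0.63). HOG strains had a median of 0.00 (percentile 49.4) and went both ways, with SSK1 at -1.89, below the background range, PBS2 at -1.17, SSK2 at -0.94 and HOG1 at 0.37. CCT2 read -0.61, CCT5 0.62 and BUD27 0.74. Of 21 lists 6 were low and 4 high by the central 95% of random lists.

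**Figure D4:**
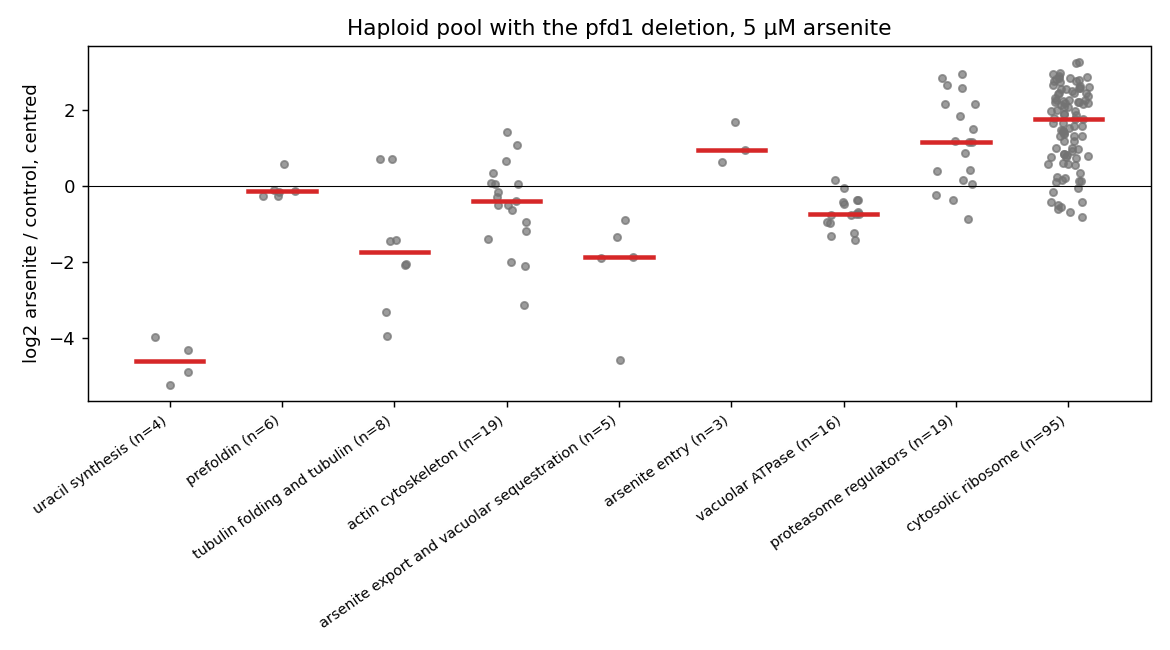
Log2 ratio of the arsenite medium without uracil over the control medium with uracil for the strains of each gene list in the pfd1 haploid pool (5 µM, 1 array); points are strains and bars are list medians. The uracil synthesis median is -4.60, the tubulin folding median -1.74 and the cytosolic ribosome median 1.78.

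Besides the uracil strains and ARR1, the largest losses were in SWC5 of the SWR1 chromatin remodeller (-6.09), PAN2 and PAN3, which form a poly(A) nuclease (-4.73 and -4.51), BIK1, a microtubule-binding protein (-4.21), and ARL3 (-4.03), which read -3.55 and -4.51 on the haploid and heterozygous 0 µM arrays and so was low without arsenite. The largest gains were in YOR302W (5.91), the short reading frame upstream of CPA1, and CPA1 itself, of carbamoyl phosphate synthesis for arginine (5.01), MUD1 (3.37), BUD21 (3.35), the exosome factors LRP1 (3.34) and RRP6 (3.24), RPS6B (3.26), RPL1B (3.24), NUP1 (3.09) and PRE9 (3.01). Among these largest losses and gains URA2, ARR1, PAN3, URA5, BIK1, YOR302W and RRP6 had more than 1 tag, and the others rest on 1.

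Across strains the haploid 800 µM array correlated with the pfd1 array at r = 0.426 (Spearman 0.368, 3943 strains), the haploid 400 µM array with the heterozygous 450 µM array at 0.325 (Spearman 0.325, 4045 strains), and the heterozygous 450 µM array with the pfd1 array at 0.203 (Spearman 0.204, 4424 strains). The haploid and heterozygous 0 µM arrays, which hold no arsenite effect, correlated at 0.457. With the 0 µM array of the haploid or heterozygous pool subtracted where there is one, the values were 0.374, 0.17 and 0.122. These are correlations across strains, which are not independent replicates, and no p-value was computed.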

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

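All tests in this part were chosen after the result was seen, except the median slope of strains deleted for a direct neighbour of a called gene, whose bounds were written before the data were examined; called neighbours, left out at first, were added to it later.

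Of 3897 strains with a value on the haploid 400 and 800 µM arrays and the pfd1 array, 9 lay outside the background range on opposite sides in the haploid and pfd1 pools. Of these 4 belong to the genes and lists given elsewhere; the others were DEG1, ITR1, PDX1, PEX10 and SAP155, lower in the haploid and higher in the pfd1 pool. ALF1 read 1.68 and 2.36 in the haploid pool and -2.04 in the pfd1 pool. BUL1 read -4.72 and -4.85 against 1.42, IRA1 -3.64 and -5.89 against 1.61, and IRA2 -4.34 and -4.40 against 2.84. The background range comes from the haploid 0 µM array, and the pfd1 array spread more widely (robust SD across strains 0.534 against 0.297). BUL1's value of 1.42 lay inside the central 90% of the pfd1 array (-1.302 to 1.453), so its opposite side is weakly held. The other strains lay outside that central 90%. The difference was not tested, and dose, PFD1 and uracil all differ between these arrays.

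Probes without a gene in the annotation also left the background range of the named strains. Below it lay 25 of 745 such probes at 400 µM and 49 of 697 at 800 µM, against 3 of 678 at 0 µM; outside it on either side lay 4.7%, 16.79% and 1.47%. Which strains they report is not given in the sources used here.

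The haploid 1600 µM array stood apart, with more strains above the background range than below it. Strains already below that range at 800 µM had no value at 1600 µM more often than those inside it (64.1% of 468 against 30.6% of 3197, a ratio of 2.09 ± 0.09), as a floor of the arsenite channel would give. The 10 highest strains made up 53.2% of the summed ratios there, against 3.1% at 800 µM and 1.0% at 0 µM, so a few survivors could hold much of that channel. Both readings rest on the direction of the ratio. With the sign turned, the strains short of values at 1600 µM would be those gained under arsenite, which a floor of the arsenite channel would not give. The shares would then be 2.0% at 1600 µM and 9.6% at 800 µM. Ratios also do not weigh a strain by its abundance. Whether an offset of the whole array contributed cannot be told apart, since the slope of the 1600 µM on the 800 µM values was 0.278 ± 0.032 among 1252 low strains, between the bounds set for either answer, and stronger killing at this dose was not tested.

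Cytosolic ribosome strains were relatively enriched at 800 µM. A dye or tag bias is argued against by their median at 0 µM, 0.04 times that at 800 µM (0.09 over 67 strains against 2.26 over 69). An advantage shared by all slow-growing strains was not seen in the mitochondrial ribosome strains, whose median slope was -0.34 ± 0.04 (40 strains). That does not decide the question, since no growth rate was measured and these strains could be sensitive to arsenite for their own reason. No biological explanation was tested.

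Many heterozygous strains of chromosome arm III right were low at 450 µM, 22 of 77 below -1 and at most 7 in any run of 77 neighbouring strains elsewhere, while the arm's median of -0.265 was no lower than the lowest run elsewhere (-0.27). A loss of all strains of the arm is argued against, since 45.5% of them lay below -0.5 (exact 95% interval 34.1% to 57.2%) and 41 of 77 above -0.3. Position within the arm was not tested and stays open. From ABP1 to AAD3, at the end of the arm, no measured strain lay below ADH7 at -0.275. Unaffected strains such as ARE1 (0.325) also lay between low ones. A fault in a single tag of each strain is argued against as well, since strains below -0.5 in a tag set had a median of -1.12 ± 0.15 in the other (33 readings), and the arm's median on the heterozygous 0 µM array was 0.015. A fault shared by both tags of a strain stays open, because the median of -0.54 ± 0.19 of the low strains on the haploid 400 µM array (28 strains) lies at the bound set and arsenite sensitivity would lower it too. A shared change in strains that were built together could also give the median of -1.11 over the 35 low strains; no construction batch is given in the sources used here, and no biological explanation was tested.

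The number of strains following dose was set against other orders of the same arrays. From 0 to 800 µM only 1 of 60 orders, the real one, gave as many calls (116 against at most 1 in any other). That argues against chance in the order of these arrays, but 60 orders of unreplicated arrays cannot exclude it. The 5 arrays were also chosen after the 1600 µM array was seen to stand apart, which favours the real order. Spread across strains rose with each dose (SD 0.40 at 0 µM and 1.23 at 800 µM). Any factor of the whole array that rose with dose would favour the real order as well. From 0 to 1600 µM all 100 orders drawn gave 0, as the real order did, and with a real count of 0 the orders decide nothing about chance.

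Whether a deletion weakened the gene next to it was read from the strains of direct neighbours of the 108 called genes. Their median slope was -0.016 (126 strains, 7 of them called; the central 95% of 10000 random sets ran from -0.02 to 0.032), which leaves this open, since each set holds the uninvolved neighbour too and essential neighbours have no value. Of 42 called genes with both neighbours measured at 800 µM, 13 (31.0%, exact 95% interval 17.6% to 47.1%) had a neighbour below the background range. That argues against it as the source of most losses among these genes, and it stays open for the others.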

How the results depend on the processing

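The 5-array fit, the fit to the same probes, the naming of tag sets and the fit without chromosome arm III right were chosen after the result was seen; the other alternatives here were fixed beforehand. The cause was not tested for any change given here, except where fewer arrays or strains enter by construction.

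For strains following dose from 0 to 1600 µM (0 lower, 0 higher), the calls were 227 lower and 502 higher with dose in µM, 175 and 17 without centring, 24 and 20 after quantile normalization, 2 and 15 after division by the median absolute deviation, and 4 lower with a minimum of 4 arrays. Leaving out each array gave 0 to 108 lower and 0 to 8 higher, the highest without the 1600 µM array.

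From 0 to 800 µM (108 lower, 8 higher), they were 554 and 474 with dose in µM, 79 and 5 with log2 of the dose plus 100 µM, 43 and 32 after quantile normalization, 145 and 49 after division by the median absolute deviation, 152 and 15 without centring, 66 and 3 with tag set 2 alone (107 and 12 with tag set 1), 95 and 4 with a minimum of 4 arrays, 28 and 2 with tags within 1 log2 unit, where 1700 strains were tested, and 85 and 17 with the same probes at every dose. limma called 0 and 0 with the arsenite arrays against the 0 µM array (36 and 20 at an unadjusted p under 0.05) and 0 and 0 with a trended and robust prior (626 and 492). Leaving out each array gave 7 to 108 lower and 0 to 8 higher.

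With an estimated correlation camera called 0 lists lower and 0 higher from 0 to 800 µM (10 and 2 at the preset one) and 0 higher from 0 to 1600 µM (1 at the preset one). From 0 to 800 µM the estimate lay below the preset one for tubulin (-0.136), export (-0.132), actin (-0.065) and ESCRT (-0.064). It lay above the preset one for the other lists called. Lost calls in those 4 lists therefore do not show correlated strains. Without centring 3 lists fell from 0 to 1600 µM. Leaving out each array gave 0 to 10 lists lower and 1 to 2 higher in the 6-array fit, and 9 to 11 and 2 to 3 in the 5-array fit.

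With the central 95% of the 0 µM array as the background range, the strains below and above it were 143 and 93 at 100 µM, 223 and 111 at 200 µM, 528 and 152 at 400 µM, 796 and 592 at 800 µM, and 452 and 555 at 1600 µM. With the 0 µM array subtracted and a fixed size of 1 log2 unit, 27 strains lay above at 100 µM and 261 below at 1600 µM. The CCT chaperonin median in the heterozygous pool was -0.81 with tag set 1 alone. Subtracting the haploid 0 µM array gave a prefoldin median of 0.10 in the pfd1 pool. The export median in the heterozygous pool was -0.55 from the 450 µM array alone, and the prefoldin median there -0.10 with tag set 1 and -0.14 with tag set 2, within their errors of 0.58 and 0.19. Correlations across strains after subtracting 0 µM arrays were 0.17 (haploid 400 µM and heterozygous), 0.374 (haploid 800 µM and pfd1) and 0.122 (heterozygous and pfd1); the Spearman value of the second was 0.368.

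Single slopes were followed under the alternatives only for named strains, not for all called strains. No called slope among those followed changed sign, and the other called slopes were not checked for this. The prefoldin median in the pfd1 pool, which was not called, went from -0.14 to 0.10. The side with more calls from 0 to 1600 µM differed between alternatives. Counted once per strain and alternative, the slopes followed kept their side of the threshold in 359 cases, no longer passed in 156 and newly passed in 17. Only a called slope can be among the 156, while the 359 include slopes that were never called. Counted once per strain or list and alternative, heterozygous values stayed within their error in 239 cases and moved in 42, and pfd1 values in 139 and 48. No paired analysis was possible because each group has 1 array. In the haploid pool 3713 probes had a value at 1600 µM and 7472 at 200 µM; signal over background was not analysed here.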

Other observations

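All gene groups in this part were put together after the values were seen, so their percentiles among random lists describe them and test nothing. Dynein and dynactin strains, which lack the motor that moves the spindle along microtubules, had a median slope of -0.56 per dose step from 0 to 800 µM (10 strains, percentile 0.00), with NIP100 steepest at -1.12 ± 0.15 (limma adjusted p = 0.0356), and a median of -1.28 in the pfd1 pool (11 strains, percentile 0.01). The spindle checkpoint had a median of -2.46 in the pfd1 pool (6 strains, percentile 0.00), led by MAD2 at -3.53 and MAD1 at -2.90, but a median slope of 0.07 in the haploid pool. Strains of SWR1, which places the histone variant H2A.Z in chromatin, had a median of -2.11 in the pfd1 pool (8 strains, percentile 0.00), but the list was split. Below the background range lay 4 of the 8, among them the H2A.Z gene HTZ1 at -3.72 and SWR1 at -3.42. Inside it lay ARP6 (-0.80), VPS71 (-0.16), SWC7 (-0.10) and SWC3 (0.08).

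No strain of nonsense-mediated decay or of the SKI complex, both of RNA surveillance, passed limma's threshold (adjusted p from 0.0626 to 0.189). Nonsense-mediated decay strains had a median slope of 0.64 (4 strains, percentile 99.99) and a median of 1.96 in the pfd1 pool (5 strains, percentile 99.98); UPF3 read 3.98 and NAM7 3.74 at 800 µM, and the median in the heterozygous pool was 0.09 (percentile 68.3). SKI complex strains had a median slope of 0.33 (3 strains, percentile 99.1) and a median of 1.94 in the pfd1 pool (4 strains). Strains lacking brakes on Ras and protein kinase A had a median slope of -0.83 (6 strains, percentile 0.00; IRA2 -1.24 ± 0.13, limma adjusted p = 0.0243) and a median of 1.30 in the pfd1 pool (percentile 99.94). COMPASS and H2B ubiquitination strains had a median slope of -0.58 (9 strains, percentile 0.02), with BRE1 at -1.06 ± 0.11 (limma adjusted p = 0.0246) and SWD3 at -0.65 ± 0.05 (adjusted p = 0.00969). Of the complexes that act on TORC1, NPR2 and NPR3 of SEACIT read 2.59 and 1.61 at 800 µM, and SEA4, RTC1 and MTC5 of SEACAT -4.68, -3.51 and -0.29.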
